A study of Mus musculus with 6 samples.

How the data were processed

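Hearts of 10-day-old mice were profiled by RNA sequencing in 6 libraries, 3 labelled Nat10 flox/flox (a label that names loxP-flanked alleles) and 3 labelled Nat10-CKO (a label that names a conditional knockout). The labels name 3 independent biological replicates per group and do not state the Cre driver or the deleted exons. Per the labels' protocols, messenger RNA was selected on poly-T beads, the libraries were directional (dUTP in the second strand), and read pairs of 150 bp came from an Illumina NovaSeq X Plus.

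Per the series' design text, reads were aligned to GRCm39 with HISAT2 2.2.1 and assigned to genes with featureCounts 2.0.6, and the submitters' processing notes also name CASAVA and DESeq2 1.42.0. The deposited values are FPKM (fragments per kilobase of gene length, scaled by library size), 1 column per library, for 46452 genes, with the authors' coordinates and gene lengths. Whether counting used the strand, and how gene length was defined, is not given in the sources used here, so antisense and overlapping genes are uncertain. FPKM times gene length came in steps of 1 read for 100% of values in each library (tolerance 0.01 read), which gave back the reads per gene. The denominator of each library equalled a median-of-ratios size factor times the geometric mean of the library totals (ratio 1.0 in all 6), so the deposited FPKM were already scaled by size factors and not by library totals.

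Recovered reads in genes numbered 38051266, 31155521 and 36672827 in the Nat10 flox/flox libraries and 35243886, 35528342 and 35854754 in the Nat10-CKO libraries. A single read in a gene of 1 kb was worth 0.0246 to 0.0316 FPKM. Of the 11996 tested genes, 206 had a mean under 20 reads.

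Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), two-sided, over genes with a mean FPKM of at least 1 across the 6 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of mean FPKM. The design has no batch in its labels. The 48 gene lists, the rule for named genes and the alternatives other than those said to be added later were fixed before the data were examined, and 45 lists had at least 3 tested members. Lists were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists, and members were also counted after adjustment over the list alone. The rule for named genes took Nat10 first, then the 8 largest rises and 8 largest falls among protein-coding genes past the threshold whose groups did not overlap. It added up to 4 members with the smallest adjusted p of each list described (1 with the smallest p where none passed), and Nppa, Nppb, Myh6, Myh7, Atp2a2, Acta1, Col1a1, Cdkn1a, Gdf15, Xist and Ddx3y. Not every gene the rule names is reported here. Other named genes are said to be chosen after their values were seen.

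The test was tried on simulated reads for the same design, with 12178 genes tested. It recovered 73.8% of genes changed 1.5-fold, 98.5% of genes changed 2-fold and 100% of genes changed 4-fold. Of its calls 13% were false, and 3.9% among genes with at least 20 reads on average. With no change simulated it made 0 calls. The simulation gave all genes the same spread between replicates (dispersion 0.0135) and left 11986 of the 12178 genes unchanged. It held no library that stands apart, so these rates need not hold for the real data. The alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or a mean FPKM of at least 5), the scaling, the trend, array weights, voom on the recovered reads, a replicate block, each library left out, and a minimum absolute log2 fold change of 1. The planned median-of-ratios scaling moved nothing, since the deposited values already carry it. Scaling by total reads, a minimum mean of 20 reads, and leaving out both libraries that stand apart were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.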

Results

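Gene expression in the hearts of 10-day-old mice was compared between 3 libraries labelled Nat10 flox/flox and 3 labelled Nat10-CKO, a label that names a conditional knockout of the RNA acetyltransferase gene Nat10. The series addresses the role of NAT10 in heart development. Between 31155521 and 38051266 reads per library fell in genes. The mitochondrially encoded genes took 16.55%, 17.69% and 18.35% of reads in the Nat10 flox/flox libraries and 7.56%, 8.18% and 9.26% in the Nat10-CKO libraries.

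Nat10 itself (gene ID 98956, chromosome 2, 103551603 to 103593292, minus strand, GRCm39) was higher in the libraries labelled Nat10-CKO. Its level was 3.75, 4.18 and 4.71 FPKM in the Nat10 flox/flox libraries and 8.28, 8.66 and 10.2 FPKM in the libraries labelled Nat10-CKO. The means were 4.22 ± 0.481 and 9.04 ± 1.0 FPKM (SD, n = 3 per group), a 2.14-fold difference with a log2 fold change of 0.94 ± 0.12 (SE) and a limma adjusted p of 0.00142. The target gene thus goes against the label, so every direction below refers to the libraries labelled Nat10-CKO. The values are per whole gene, and reads from exons or cells in which the gene was not deleted cannot be separated in them.

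**Figure D1:**
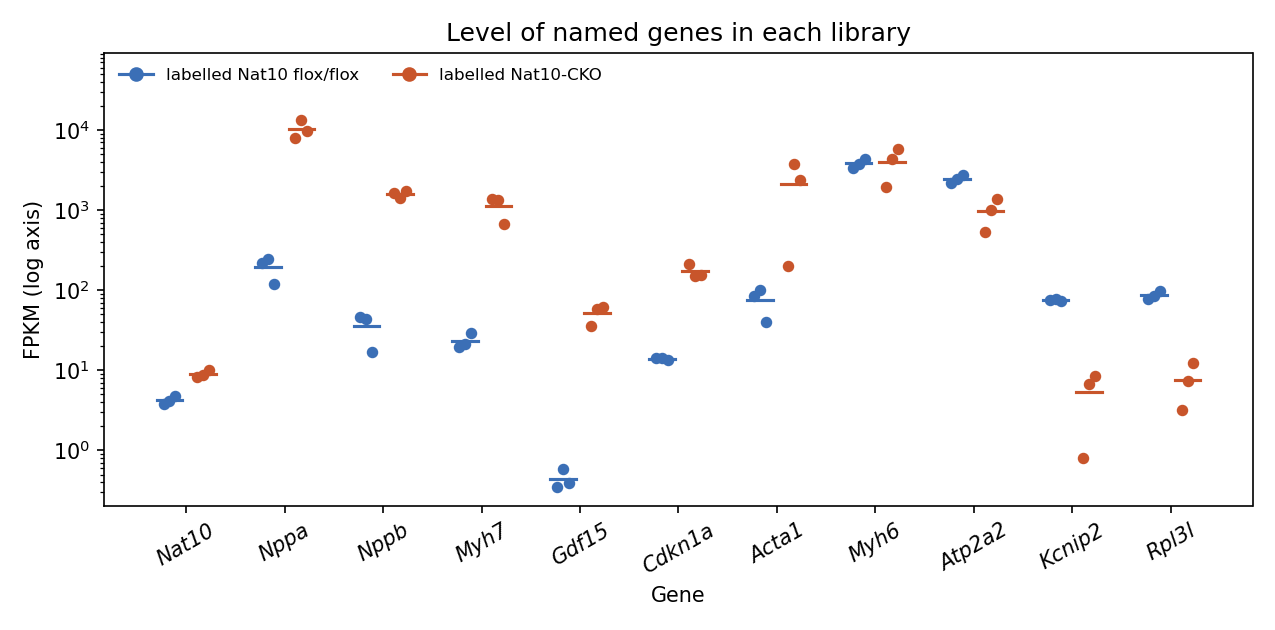
Level of named genes in each library, as FPKM on a log axis, with 1 point per library and a line at each group mean for the 3 libraries labelled Nat10 flox/flox and the 3 labelled Nat10-CKO. Nat10 lies between 3.75 and 4.71 FPKM in the former and between 8.28 and 10.2 in the latter, and Nppa between 118.7 and 242.6 against 8008 to 13520.

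Natriuretic peptide and other fetal or stress genes of heart muscle were far higher in the libraries labelled Nat10-CKO. Nppa (gene ID 230899, chromosome 4, 148085179 to 148086531, plus strand), which encodes atrial natriuretic peptide, went from 194 ± 66.3 to 10410 ± 2825 FPKM (SD, n = 3 per group, 53.6-fold). Nppb (gene ID 18158) went from 35.5 ± 16.1 to 1588 ± 168 FPKM (44.7-fold). Myh7 (gene ID 140781, chromosome 14, 55208141 to 55232083, minus strand), the slow myosin heavy chain, went from 23.3 ± 5.18 to 1130 ± 395 FPKM (48.5-fold). Of 11996 genes tested, 4856 (40.5%) passed the threshold, 2932 higher and 1924 lower, and 1520 of them had an absolute log2 fold change of at least 1. The groups did not overlap for 6704 genes (55.9%), where chance gives 10%. Higher calls made up 60.4% of calls, 48.7% with the mitochondrially encoded genes left out and the rest rescaled, and 73.4% with protein-coding genes rescaled to a common total. The latter moved the median log2 fold change of the tested genes from 0.035 to 0.178, so counts by direction are relative to the scaling. The count of lower genes was 1207 without Nat10 flox/flox replicate 2 and 1212 without Nat10 flox/flox replicate 3.

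**Figure D2:**
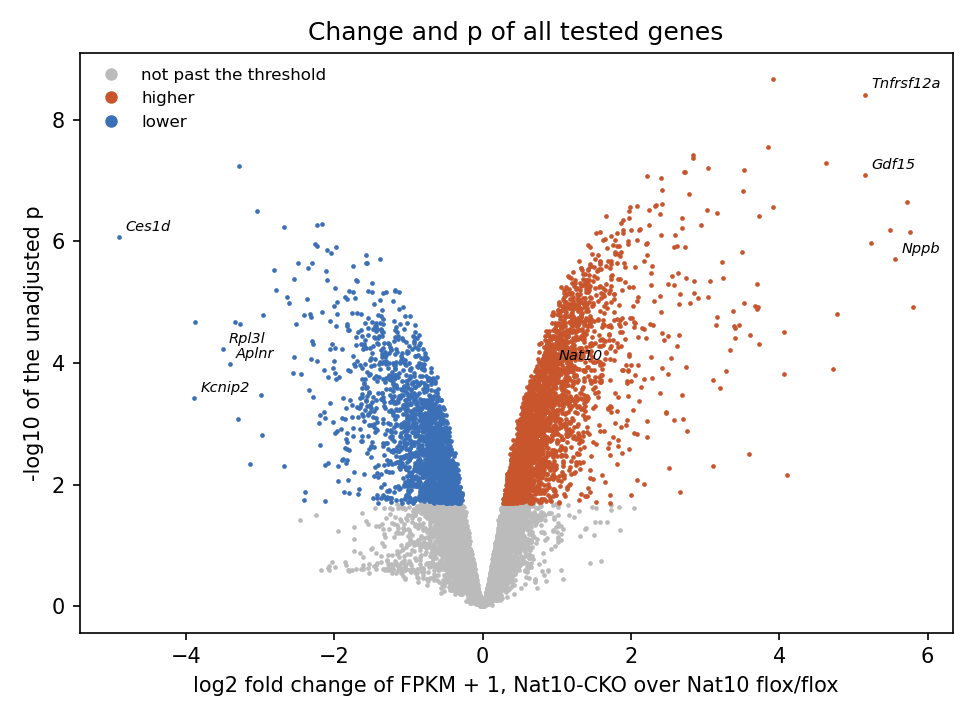
Log2 fold change of FPKM + 1 (libraries labelled Nat10-CKO over Nat10 flox/flox) on the x axis against -log10 of the unadjusted limma p on the y axis, with 1 point per tested gene. Of the 11996 points, 2932 are coloured as higher and 1924 as lower, and grey points did not pass the adjusted threshold.

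The libraries separated by label on the first principal component, which held 68.2% of the variance. Nat10 flox/flox replicate 1 stood apart on the second (14.7%) and Nat10-CKO replicate 1 on the third (10.5%). Within groups the correlation of log2 values was 0.948 to 0.987, and the 2 lowest pairs both held Nat10 flox/flox replicate 1. Without both libraries that stand apart, 4834 genes passed, 2923 higher and 1911 lower.

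The 8 largest rises among protein-coding genes were Nppa, Tent5b, Nppb, Myh7, Xirp2, Tnfrsf12a, Gdf15 and Sprr1a. Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 13.6 ± 2.09 to 514 ± 20.8 FPKM (37.9-fold, adjusted p = 2.33e-05 by limma). Xirp2, an actin-binding protein of the intercalated disc, rose from 19.4 ± 2.88 to 808 ± 312 FPKM. Gdf15, a stress-induced hormone of the TGF-beta family, rose from 0.440 ± 0.124 to 51.4 ± 13.8 FPKM (117-fold). Tent5b rose from 1.48 ± 0.806 to 126 ± 21.2 FPKM. Sprr1a had 2 reads in Nat10 flox/flox replicate 1, 0 in the other 2 Nat10 flox/flox libraries, and 1590, 698 and 371 in the Nat10-CKO libraries. The ratio of mean FPKM was 1510. The ratio of reads pooled over each group, scaled by the library denominators, was 1360, or 839 without Nat10-CKO replicate 1. Its 95% counting interval of 376 to 11200 covers counting error only. Without Nat10 flox/flox replicate 1 the pooled ratio was at least 564 against a floor of 3 reads over the group, and without replicate 2 or 3 it was 960 and 911.

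The 8 largest falls were Ces1d, Kcnip2, Ucp3, Rpl3l, Aplnr, Asb15, Mylk4 and Gm12185. Ces1d, a carboxylesterase, fell from 41.6 ± 15.7 to 0.382 ± 0.272 FPKM, and Kcnip2, a subunit of the transient outward potassium channel, from 75.3 ± 2.09 to 5.41 ± 4.09 FPKM (log2 fold change -3.89, or -3.14 without Nat10-CKO replicate 1). Rpl3l, the muscle-restricted paralogue of ribosomal protein L3, fell from 87.2 ± 9.14 to 7.63 ± 4.63 FPKM, and Ucp3, a mitochondrial carrier, from 51.2 ± 22.5 to 2.47 ± 1.16 FPKM. Aplnr, the apelin receptor, fell from 25.3 ± 3.64 to 1.78 ± 1.62 FPKM (14.2-fold, or 27.3-fold without Nat10-CKO replicate 2). Asb15 fell from 17.4 ± 0.639 to 0.950 ± 0.840 FPKM (18.4-fold, or 31.8-fold without Nat10-CKO replicate 3) and Mylk4 from 38.3 ± 14.8 to 3.73 ± 3.70 FPKM (log2 fold change -3.30, or -3.91 without Nat10-CKO replicate 3). Gm12185 was uneven among the Nat10 flox/flox libraries, at 64.7 FPKM in Nat10 flox/flox replicate 2 and 8.02 and 9.75 FPKM in the others, with a log2 fold change of -3.14 (-2.22 without that library). Its fold of means was 22.5, or 7.27 without Nat10 flox/flox replicate 2 and 39.8 without Nat10-CKO replicate 3. It missed the threshold without Nat10-CKO replicate 2 (adjusted p = 0.0565 by limma).

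Of the 45 gene lists tested, camera with a preset correlation called 19, 9 toward higher and 10 toward lower values. With an estimated correlation camera called 0, the smallest adjusted p being 0.447, and 4 lists had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 24, among them 16 of the 19. The 3 lists called by camera and not by fry were nuclear-encoded oxidative phosphorylation (fry adjusted p = 0.0951), the tricarboxylic acid cycle (0.112) and postnatal maturation (0.349). The median, mean and test of a list differed in sign for 8 lists, none of them among the 19.

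**Figure D3:**
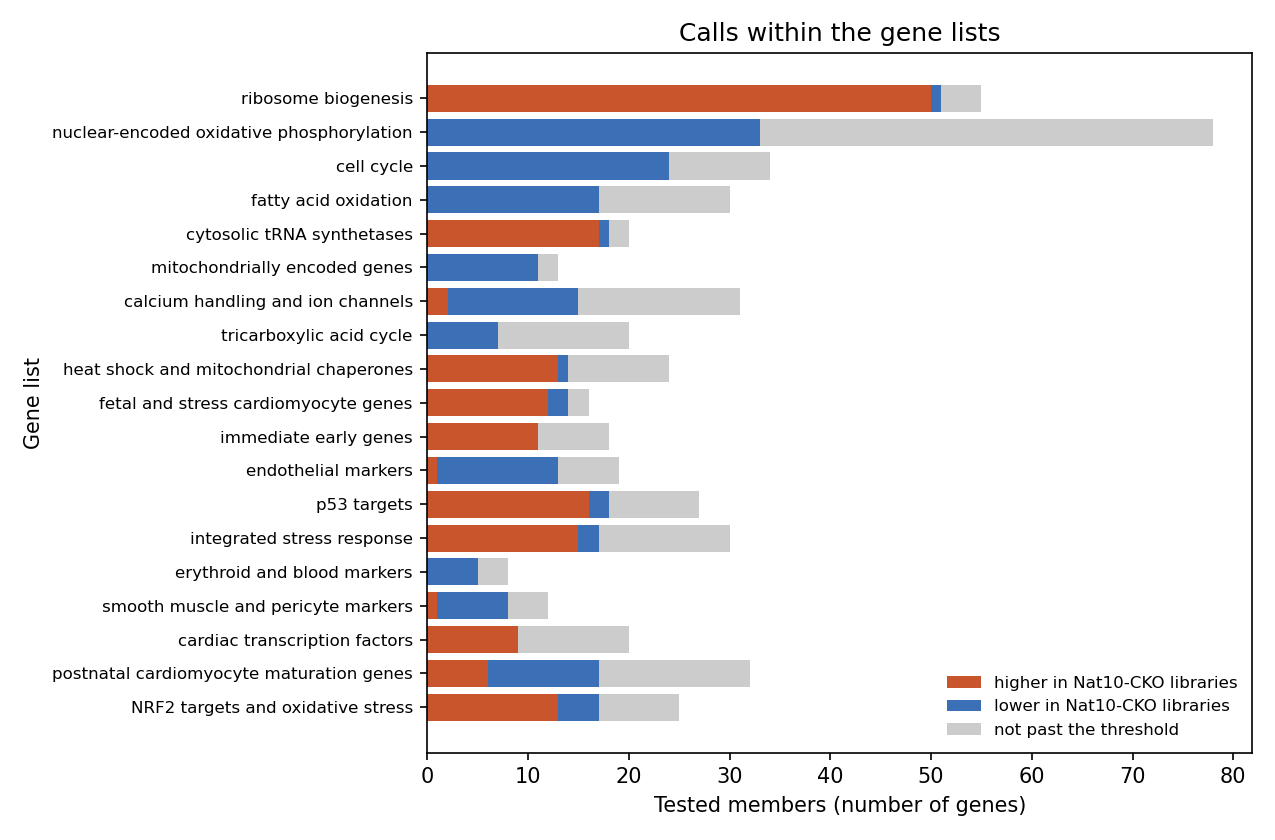
Number of tested members of the 19 gene lists called by camera with a preset correlation, split into members higher, lower or not past the threshold in the libraries labelled Nat10-CKO. Ribosome biogenesis has 50 of 55 members higher, and nuclear-encoded oxidative phosphorylation has 33 of 78 lower.

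Genes of ribosome biogenesis rose together. Of 55 tested members 50 were higher and 1 lower (51 and 2 adjusted over the list alone), with a median log2 fold change of 1.22 and a camera adjusted p of 9.03e-17 (adjusted p = 0.447 with an estimated correlation). Nop58, a core protein of box C/D small nucleolar particles, went from 8.24 ± 0.747 to 65.1 ± 2.43 FPKM, Tsr1 from 2.77 ± 0.147 to 30.2 ± 4.21 FPKM, Wdr43 from 7.72 ± 0.710 to 45.5 ± 4.43 FPKM and Nop16 from 5.73 ± 0.175 to 25.4 ± 2.18 FPKM. The genes of the cytosolic ribosomal proteins themselves were not called as a list (76 tested, 1 higher and 6 lower, 0 and 0 adjusted over the list alone; camera adjusted p = 0.102), although the list was called toward lower values without Nat10-CKO replicate 1 (adjusted p = 5.09e-05), at a mean of at least 5 FPKM (0.0174) and with array weights (0.00307). Rps29 fell from 155 ± 6.90 to 103 ± 6.78 FPKM. Thumpd1, the adaptor for tRNA acetylation by NAT10, rose 3.73-fold, from 9.08 ± 0.0693 to 33.9 ± 7.54 FPKM. It and Nat10 were the 2 tested members of a list of the acetylation machinery, both higher, also adjusted over the list alone, and too few to test.

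Cytosolic tRNA synthetase genes were higher for 17 of 20 members and lower for 1, also adjusted over the list alone (camera adjusted p = 8.04e-07; adjusted p = 0.447 with an estimated correlation). Rars rose from 15.7 ± 0.559 to 59.0 ± 6.44 FPKM, Lars from 12.9 ± 1.17 to 56.3 ± 11.9 FPKM, Farsb from 6.33 ± 0.443 to 14.5 ± 0.0547 FPKM and Vars from 8.52 ± 0.609 to 18.7 ± 0.968 FPKM. In the integrated stress response list, the targets of ATF4, 15 of 30 members were higher and 2 lower (18 and 2 adjusted over the list alone; camera adjusted p = 0.000873; adjusted p = 0.628 with an estimated correlation). The number of higher members was 22 without Nat10-CKO replicate 1 and 10 without Nat10 flox/flox replicate 2. Ppp1r15a, which promotes dephosphorylation of eIF2, rose from 7.48 ± 1.45 to 67.3 ± 5.02 FPKM, and the amino acid transporter genes Slc7a5 and Slc3a2 rose 7.42-fold and 3.11-fold.

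Targets of p53 were higher for 16 of 27 members and lower for 2 (17 and 3 adjusted over the list alone; camera adjusted p = 0.000819; adjusted p = 0.447 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 12.3-fold to 173 ± 35.5 FPKM. Phlda3 rose from 12.4 ± 0.554 to 91.5 ± 12.4 FPKM and Aen from 6.78 ± 0.143 to 22.0 ± 2.03 FPKM. Cell cycle genes fell for 24 of 34 members and rose for 0, also adjusted over the list alone (camera adjusted p = 4.47e-08; adjusted p = 0.625 with an estimated correlation). Cenpf went from 2.69 ± 0.581 to 0.0795 ± 0.0552 FPKM (33.8-fold, or 51.6-fold without Nat10-CKO replicate 2). Top2a fell from 4.26 ± 1.14 to 0.588 ± 0.299 FPKM, Ccna2 from 2.66 ± 0.808 to 0.340 ± 0.0927 FPKM and Ube2c from 5.70 ± 1.48 to 1.71 ± 0.0713 FPKM. These genes are low. With a minimum mean of 5 FPKM only 8 cell cycle members were tested, of which 3 were called lower. The list then missed the camera threshold (adjusted p = 0.119).

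Immediate early genes were higher for 11 of 18 members and lower for 0 (12 and 0 adjusted over the list alone; camera adjusted p = 0.000698; adjusted p = 0.526 with an estimated correlation). Myc rose from 2.66 ± 0.199 to 16.1 ± 0.680 FPKM, Atf3 from 4.94 ± 1.10 to 81.3 ± 34.8 FPKM, Nr4a1 4.46-fold and Jund 2.16-fold. Heat shock and mitochondrial chaperones were higher for 13 of 24 members and lower for 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.000601; adjusted p = 0.567 with an estimated correlation). The small heat shock protein gene Hspb1 rose from 144 ± 8.67 to 1641 ± 683 FPKM, Hspb7 3.68-fold, Bag3 3.85-fold and Hspa4 2.75-fold. Targets of NRF2 were higher for 13 of 25 members and lower for 4, also adjusted over the list alone (camera adjusted p = 0.0371; adjusted p = 0.799 with an estimated correlation). Txnrd1 rose 3.17-fold, the metallothionein genes Mt1 2.20-fold and Mt2 5.33-fold, while Prdx3, a mitochondrial peroxiredoxin, fell from 140 ± 6.86 to 65.4 ± 14.4 FPKM. The NRF2 list had 8, 7 and 8 higher members without Nat10 flox/flox replicate 1, 2 and 3 and missed the threshold without replicate 2 (adjusted p = 0.0508), under quantile normalization (0.11), with protein-coding genes rescaled (0.126) and at a mean of at least 5 FPKM (0.153).

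The fetal and stress genes of cardiomyocytes were higher for 12 of 16 members and lower for 2, also adjusted over the list alone (camera adjusted p = 0.000698; adjusted p = 0.526 with an estimated correlation). Besides Nppa, Nppb, Myh7 and Xirp2, Rcan1, a calcineurin regulator and target, rose from 23.7 ± 2.04 to 286 ± 39.2 FPKM. Skeletal alpha-actin, Acta1, was 85.7, 101 and 39.9 FPKM in the Nat10 flox/flox libraries and 201, 3819 and 2393 FPKM in the libraries labelled Nat10-CKO (adjusted p = 0.0223 by limma). Its log2 fold change of 4.11 became 5.41 without Nat10-CKO replicate 1, and it missed the threshold without Nat10 flox/flox replicate 1 (adjusted p = 0.0535), 2 (0.0521) or 3 (0.0745) and without Nat10-CKO replicate 2 (0.0652) or 3 (0.0663). Myh6, the fast myosin heavy chain, was 3397, 3817 and 4385 FPKM against 1958, 4401 and 5767 FPKM and did not pass (log2 fold change -0.07 ± 0.40 SE, adjusted p = 0.91 by limma). Its sign turned without Nat10-CKO replicate 1 (0.39) or without Nat10 flox/flox replicate 3 (0.03), under quantile normalization (0.18) and with protein-coding genes rescaled (0.09). Sarcomere genes were not called as a list (30 tested, 14 higher and 3 lower, also adjusted over the list alone; camera adjusted p = 0.0902). They were called toward higher values without Nat10-CKO replicate 1 (0.0189), without Nat10 flox/flox replicate 3 (0.0464), under quantile normalization (0.0342), with no filter (0.00264) and by fry (0.0187). Synpo2l rose from 33.0 ± 4.82 to 847 ± 158 FPKM, Myot 8.04-fold, Flnc 11.4-fold and Csrp3 3.70-fold.

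Cardiac transcription factors were higher for 9 of 20 members and lower for 0 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0255; adjusted p = 0.628 with an estimated correlation). Nkx2-5 rose from 41.9 ± 3.05 to 166 ± 12.3 FPKM, Gata4 from 35.1 ± 2.96 to 107 ± 20.4 FPKM, Tbx20 2.21-fold and Srf 2.05-fold. Postnatal maturation genes were lower for 11 of 32 members and higher for 6 (12 and 6 adjusted over the list alone; camera adjusted p = 0.0371; adjusted p = 0.872 with an estimated correlation). Tnni3, the adult cardiac troponin I, fell from 1660 ± 110 to 559 ± 151 FPKM, and Pln, phospholamban, from 2137 ± 267 to 604 ± 241 FPKM. The maturation list had 6 lower members without Nat10 flox/flox replicate 2 and 6 without replicate 3, and its call was lost without Nat10 flox/flox replicate 3 (adjusted p = 0.0586), without Nat10-CKO replicate 1 (0.052), under quantile normalization (0.0731), with mitochondrially encoded genes left out (0.0639) and with no filter (0.125).

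Calcium handling and ion channel genes were lower for 13 of 31 members and higher for 2 (15 and 2 adjusted over the list alone; camera adjusted p = 0.000518; adjusted p = 0.716 with an estimated correlation). The inward rectifier gene Kcnj2 fell from 9.24 ± 2.14 to 0.972 ± 0.309 FPKM, Kcnj3 from 5.72 ± 0.649 to 0.558 ± 0.243 FPKM and the connexin gene Gjc1 from 10.5 ± 0.452 to 5.01 ± 0.439 FPKM. Atp2a2, the calcium pump SERCA2, fell from 2452 ± 277 to 985 ± 429 FPKM (adjusted p = 0.0173 by limma), with an adjusted p of 0.0576 without Nat10 flox/flox replicate 2 and 0.0613 without replicate 3.

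Genes of fatty acid oxidation were lower for 17 of 30 members and higher for 0 (20 and 0 adjusted over the list alone; camera adjusted p = 1.78e-07; adjusted p = 0.628 with an estimated correlation). Hadhb fell from 180 ± 23.6 to 45.2 ± 13.5 FPKM, Cpt2 from 90.1 ± 9.70 to 31.0 ± 9.89 FPKM and the fatty acid transporter gene Slc27a1 from 64.5 ± 6.76 to 24.6 ± 3.15 FPKM. The list had 10 lower members without Nat10 flox/flox replicate 3 and 10 without Nat10-CKO replicate 2. Nuclear-encoded genes of oxidative phosphorylation were lower for 33 of 78 members and higher for 0 (35 and 0 adjusted over the list alone; camera adjusted p = 6.06e-10; adjusted p = 0.827 with an estimated correlation), with a median log2 fold change of -0.58. Ndufa4 fell from 824 ± 23.3 to 269 ± 97.7 FPKM, Ndufc2 from 160 ± 13.0 to 80.3 ± 16.9 FPKM, Atp5g3 from 732 ± 36.8 to 395 ± 71.2 FPKM and Ndufa1 from 94.8 ± 8.94 to 49.7 ± 10.3 FPKM. The number of lower members was 13, 9 and 9 without Nat10 flox/flox replicate 1, 2 and 3, and 14 and 53 without Nat10-CKO replicate 2 and 3.

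All 13 mitochondrially encoded protein genes were tested, 11 were lower and 0 higher (12 and 0 adjusted over the list alone; camera adjusted p = 1.4e-06; adjusted p = 0.567 with an estimated correlation). COX2 fell from 1365 ± 20.2 to 512 ± 64.2 FPKM, ND2 from 13890 ± 1753 to 4511 ± 447 FPKM and ND3 from 266 ± 121 to 42.9 ± 11.5 FPKM. ND6, at 7897 ± 1031 and 3086 ± 542 FPKM, lies on the strand opposite to its neighbours, so its level is uncertain without the strand setting. Genes of the tricarboxylic acid cycle were lower for 7 of 20 members and higher for 0, also adjusted over the list alone (camera adjusted p = 0.000518; adjusted p = 0.837 with an estimated correlation). Cs, citrate synthase, fell from 522 ± 54.9 to 259 ± 55.3 FPKM, Sdhb from 553 ± 44.7 to 243 ± 72.7 FPKM and Suclg2 from 29.9 ± 4.69 to 11.3 ± 1.74 FPKM. The cycle list had 4 and 3 lower members without Nat10 flox/flox replicate 2 and 3, and 4 and 11 without Nat10-CKO replicate 2 and 3. Glycolysis was not called (25 tested, 10 higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.274; 0.044 with no filter and 0.0138 by fry, both toward higher values), but the glucose transporter gene Slc2a1 rose from 6.74 ± 0.812 to 26.9 ± 3.54 FPKM and Hk1 2.20-fold. Genes of mitochondrial maintenance and translation were not called (28 tested, 3 higher and 3 lower, 3 and 2 adjusted over the list alone; camera adjusted p = 0.846).

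Endothelial markers were lower for 12 of 19 members and higher for 1, also adjusted over the list alone (camera adjusted p = 0.000819; adjusted p = 0.567 with an estimated correlation). Kdr, the VEGF receptor, fell from 35.3 ± 6.27 to 9.67 ± 0.476 FPKM. Cdh5 fell to 44.6 ± 6.99 FPKM (log2 fold change -1.08) and Egfl7 from 71.0 ± 3.27 to 39.6 ± 1.20 FPKM. Markers of smooth muscle and pericytes were lower for 7 of 12 members and higher for 1, also adjusted over the list alone (camera adjusted p = 0.00607; adjusted p = 0.447 with an estimated correlation). Vtn fell from 21.7 ± 4.03 to 4.62 ± 1.35 FPKM, Smtn 3.14-fold, Abcc9 2.61-fold and Kcnj8 1.80-fold. Erythroid markers were lower for 5 of 8 members (7 adjusted over the list alone; camera adjusted p = 0.00576; adjusted p = 0.567 with an estimated correlation), and 3, 1 and 1 members were past the threshold without Nat10 flox/flox replicate 1, Nat10 flox/flox replicate 2 and Nat10-CKO replicate 2. Hbb-bt went from 47.0 ± 22.8 to 11.6 ± 2.86 FPKM.

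Extracellular matrix genes were not called by camera (39 tested, 15 higher and 2 lower, 16 and 4 adjusted over the list alone; adjusted p = 0.0534). They were called toward higher values without Nat10-CKO replicate 3 (6.72e-05), without Nat10 flox/flox replicate 2 (0.041), with a pseudocount of 0.1 (0.0375) or 0.5 (0.0453), with no filter (0.000238), with mitochondrially encoded genes left out (0.026) and with array weights (0.00299). Timp1 rose from 2.66 ± 0.662 to 43.0 ± 17.7 FPKM, Ccn2 13.9-fold, Thbs1 13.3-fold (8.84-fold without Nat10-CKO replicate 1) and Tgfb2 6.41-fold. Col1a1 was 64.5, 65.8 and 59.1 FPKM against 152, 125 and 54.2 FPKM (adjusted p = 0.182 by limma; 0.00378 without Nat10-CKO replicate 3). Fibroblast markers (13 tested, 2 higher and 2 lower, also adjusted over the list alone; camera adjusted p = 0.882) and macrophage markers (24 tested, 2 higher and 2 lower, 0 and 0 adjusted over the list alone; 0.882) were not called. Of these, Mfap5 rose 3.38-fold and Dpt fell from 36.2 ± 3.90 to 22.0 ± 4.68 FPKM (adjusted p = 0.0659 without Nat10 flox/flox replicate 2 and 0.0654 without replicate 3). H2-Ab1 of MHC class II and its invariant chain gene Cd74 fell 4.30-fold and 4.05-fold, or 2.62-fold and 2.55-fold without Nat10 flox/flox replicate 2, the highest library. Cd74 missed the threshold with no filter (adjusted p = 0.0512). Lgals3 and Gpnmb rose 3.21-fold and 7.18-fold, Gpnmb 3.56-fold without Nat10-CKO replicate 1. Lgals3 missed the threshold without Nat10 flox/flox replicate 1 (0.0675), 2 (0.0943) or 3 (0.119) and without Nat10-CKO replicate 1 (0.0532) or 2 (0.102). Gpnmb missed it without Nat10 flox/flox replicate 1 (0.091), 2 (0.126) or 3 (0.0813) and without Nat10-CKO replicate 2 (0.0595). Lymphocyte markers held 0 called members of 10 (0 adjusted over the list alone; camera adjusted p = 0.0619), and the list was called without Nat10 flox/flox replicate 1 (0.0372), without Nat10 flox/flox replicate 3 (0.0067) and without Nat10-CKO replicate 1 (0.0458), with no filter (0.012) and with array weights (0.0407). Schwann cell and neuron markers held 0 called members of 9 (0 adjusted over the list alone; camera adjusted p = 0.195; 0.0328 without Nat10 flox/flox replicate 3).

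Interferon response genes were not called (30 tested, 1 higher and 0 lower, 0 adjusted over the list alone; camera adjusted p = 0.871), but were without Nat10-CKO replicate 1 (0.00936). Ifit1 was 21.3, 23.8 and 16.4 FPKM against 34.0, 115 and 179 FPKM, with a log2 fold change of 2.08 (2.76 without Nat10-CKO replicate 1). It missed the threshold without Nat10 flox/flox replicate 1 (adjusted p = 0.0625), 2 (0.0607) or 3 (0.0813) and without Nat10-CKO replicate 2 (0.0826) or 3 (0.0554). Cytokines and chemokines were not called (21 tested, 6 higher and 3 lower, also adjusted over the list alone; camera adjusted p = 0.721; 0.0347 by fry toward higher values). Lcn2 rose to 58.7 ± 45.9 FPKM (log2 fold change 4.07, or 3.47 without Nat10-CKO replicate 1), and Cxcl12 fell 1.76-fold. Cholesterol and fatty acid synthesis was not called (24 tested, 2 higher and 5 lower, 1 and 5 adjusted over the list alone; camera adjusted p = 0.0619). It was called toward lower values without Nat10 flox/flox replicate 2 (0.0127) or 3 (0.015) and with protein-coding genes rescaled (0.0354). Its member Fdft1 fell 4.97-fold and Fasn rose (log2 fold change 0.80).

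Further lists were not called by camera. Intercalated disc and cytoskeleton genes had 11 higher and 4 lower of 27 members (13 and 6 adjusted over the list alone; adjusted p = 0.228, or toward higher values 0.0102 with no filter and 0.00354 by fry), and Pkp2 of the desmosome rose 3.67-fold. Neurohormonal and growth factor signalling had 4 higher and 7 lower of 22 (5 and 7 adjusted over the list alone; 0.272, or toward lower values 0.0107 at a mean of at least 5 FPKM and 0.00313 by fry). The adrenergic receptor gene Adra1b fell 4.25-fold and Igf1r rose (log2 fold change 1.11). Cell death machinery had 8 higher and 4 lower of 28, also adjusted over the list alone (0.605), and Bcl2l1 rose 2.96-fold. Autophagy and lysosome genes had 7 higher and 7 lower of 28, also adjusted over the list alone (0.882, or 0.0457 by fry toward higher values), and the autophagy receptor gene Sqstm1 rose 3.05-fold. Chaperones of the endoplasmic reticulum had 4 higher and 3 lower of 24 (2 and 1 adjusted over the list alone; 0.882). Hypoxia and angiogenic factors had 4 higher and 3 lower of 20, also adjusted over the list alone (0.721, or 0.0347 by fry toward higher values).

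Among markers of other cell types, epicardial genes had 2 higher and 1 lower of 6 (4 and 1 adjusted over the list alone; camera adjusted p = 0.255, or 0.0451 by fry toward higher values). Valve genes had 3 higher and 1 lower of 7, also adjusted over the list alone (0.459), and lymphatic endothelial genes 2 higher of 6 (1 adjusted over the list alone; 0.575). Neutrophil and mast cell markers had 1 lower of 5, also adjusted over the list alone (0.696). Atrial and conduction markers had 2 higher and 2 lower of 10 (3 and 2 adjusted over the list alone; 0.749), and adipocyte markers 1 lower of 3 (1 higher and 1 lower adjusted over the list alone; 0.882). Replication-dependent histones had 2 higher and 1 lower of 5, also adjusted over the list alone (0.882). Skeletal muscle markers (2 tested, 1 lower) and thymus and lung markers (1 tested, 1 lower), with the same counts adjusted over the list alone, were too few to test.

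Xist was at 0.110, 0.0212 and 0.0314 FPKM in the Nat10 flox/flox libraries and 0.00606, 0.0129 and 0.00328 FPKM in the libraries labelled Nat10-CKO. Ddx3y, on the Y chromosome, was 13.9, 13.7 and 14.9 FPKM against 19.4, 14.7 and 21.5 FPKM (adjusted p = 0.0992 by limma), and it passed without Nat10-CKO replicate 2 (0.0261). A Y-linked transcript was thus measured in all 6 libraries. Of 4 tested sex-linked genes, Kdm5d and Eif2s3y were higher (2 adjusted over the list alone; camera adjusted p = 0.357 for the list). Kdm5d missed the threshold without Nat10 flox/flox replicate 1 (adjusted p = 0.0528) or 2 (0.0536) and without Nat10-CKO replicate 2 (0.0518). Eif2s3y missed it without Nat10 flox/flox replicate 1 (0.159), 2 (0.0975) or 3 (0.122) and without Nat10-CKO replicate 1 (0.0819), 2 (0.0871) or 3 (0.0917).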

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

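Scaling by total reads, a minimum mean of 20 reads and leaving out both libraries that stand apart were chosen after the data were seen. Nat10 kept its direction and its call in all 21 alternatives (log2 fold change 0.845 to 1.102), of which median-of-ratios scaling moved nothing. The minimum absolute log2 fold change of 1 is not among the 21, and Nat10 (0.943) lies under it. Of 163 called named genes, 134 kept call and direction in all 21, and 29 lost the call in at least 1. Of the 4856 calls, 0 changed sign in an alternative that tested them. Of the calls, 37 had a mean under 20 reads, where simulated false calls gathered, and a minimum of 20 reads gave 4862 genes. A minimum absolute log2 fold change of 1 left 1520 genes, 960 higher and 560 lower, by construction. With an estimated correlation 0 gene lists were called, and with fry 24. With no filter on low values, members called lower were 10 for nuclear-encoded oxidative phosphorylation, 10 for fatty acid oxidation, 4 for mitochondrially encoded genes, 4 for the tricarboxylic acid cycle, 1 for erythroid and 5 for maturation genes. At a mean of at least 5 FPKM, where fewer genes are tested, 1159 genes were lower and 3 of 8 tested cell cycle members. With mitochondrially encoded genes left out, oxidative phosphorylation had 57 and the tricarboxylic acid cycle 12 lower members. Array weights gave 3007 lower genes, 61 and 12 lower members of these lists, 24 higher integrated stress response members and 8 lower erythroid members. Scaling by total reads gave 11 lower members of the tricarboxylic acid cycle, and without both libraries that stand apart 3 erythroid members were lower. The cause of these differences was not tested. Myh6 turned to 0.184 under quantile normalization, 0.091 with protein-coding genes rescaled, 0.16 with array weights and 0.3 without both libraries that stand apart, and ranged from -0.389 to 0.39 with each library left out. Over the same 6 fits, lower genes ranged from 1207 to 1924, and called members from 9 to 53 (oxidative phosphorylation), 10 to 20 (fatty acid oxidation), 3 to 11 (tricarboxylic acid cycle), 1 to 6 (erythroid), 6 to 13 (maturation) and 7 to 15 (NRF2). With the replicate number as a block, 4390 genes passed (2666 higher, 1724 lower), and the extracellular matrix and lymphocyte lists were called (adjusted p = 0.0278 for each). Scaling by total reads called the extracellular matrix list (0.0452). Without both libraries that stand apart, the sarcomere (0.0471) and interferon (0.0169) lists were called toward higher and the ribosomal protein (7.1e-05) and lymphocyte (0.0327) lists toward lower values. The labels name independent replicates and state no pairing by number. Deviations of same-numbered libraries correlated at 0.065, 0.037 and 0.105, and 4 of 6 libraries correlated best with their own number. These values do not settle whether the samples were paired.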

Other observations

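The tests of exchanged labels, run-on reads from Caprin1, ribosome biogenesis, ganglion or nerve tissue, cardiomyocyte share, scaling and splits of the libraries were chosen after the result was seen, and those of depth and gene length before. Genes named here beyond the fixed rule were chosen after their values were seen.

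At the Myh7 locus on chromosome 14, Mhrt and Gm31251 overlap Myh7 on the opposite strand, and Myh6 beside it did not pass the threshold. Mhrt, a noncoding RNA, fell from 26.6 ± 3.40 to 9.19 ± 4.24 FPKM (SD, n = 3 per group, adjusted p = 0.0111 by limma) and Gm31251 from 10.6 ± 2.45 to 2.75 ± 1.05 FPKM, while Myh7 rose 48.5-fold. The value of Mir208b, a microRNA gene within Myh7 on the same strand, also fell, from 293 ± 37.0 to 31.4 ± 12.7 FPKM. That gene is 77 bases long, shorter than a read of 150 bp, and the libraries were made from poly-T selected RNA. Its value is therefore no measure of the microRNA itself. At the Myh6 locus, where Myh6 itself did not pass, 2 genes fell as well. Gm52092, within Myh6 on the opposite strand, fell from 17.0 ± 1.76 to 2.84 ± 1.82 FPKM (adjusted p = 0.00247 by limma). Mir208a, a microRNA gene of 83 bases within Myh6 with the same limit, fell from 8.82 ± 2.85 to 3.21 ± 0.516 FPKM. The falls were thus not confined to the locus of Myh7, the myosin gene that rose. The levels of Mhrt, Gm31251, Gm52092, Mir208b and Mir208a are uncertain without the strand setting of the counting. Apln, which encodes the ligand of Aplnr, fell from 9.20 ± 1.16 to 0.843 ± 0.621 FPKM (10.9-fold, or 18.2-fold without Nat10-CKO replicate 1). The keratin gene Krt18 rose from 0.265 ± 0.156 to 16.2 ± 6.91 FPKM.

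Nat10-CKO replicate 1 differed from the other libraries of its label. Trib3, a target of ATF4, was 2.61 FPKM there and 17.6 and 14.2 FPKM in replicates 2 and 3. Atf5 was 23.2 against 118 and 108 FPKM, and Mthfd2 5.33 against 35.4 and 20.9 FPKM. The Nat10 flox/flox means were 2.02 (Trib3), 25.1 (Atf5) and 2.88 FPKM (Mthfd2). Trib3 and Atf5 were thus near that level in Nat10-CKO replicate 1 and missed the threshold (adjusted p = 0.0523 and 0.102 by limma). Ppp1r15a and Slc7a5 of the integrated stress response list were raised there, at 65.4 and 28.8 FPKM. The interferon-induced Isg15 was 11.4 FPKM in Nat10-CKO replicate 1 against 61.2 and 71.8 FPKM. Lox, a collagen crosslinking enzyme, was 65.5 against 12.6 and 5.94 FPKM.

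The first pattern weighed is the higher Nat10 in the libraries labelled Nat10-CKO. A constant share of reads running on from the upstream neighbour Caprin1 is argued against, since Caprin1 had a log2 fold change of 0.273, below that of Nat10 by 0.67 ± 0.162 (SE). A rise of Nat10 along with the ribosome biogenesis genes is a candidate explanation, and 36.4% of that list's members had a lower log2 fold change than Nat10. The middle 95% of the list is wide (-0.305 to 2.971) and takes in the median of all tested genes (0.035). Lying within it is therefore no support for a shared rise. Among all tested genes, 90.6% had a lower log2 fold change than Nat10. By the Nat10 level alone, an exchange of the group labels of all 6 libraries cannot be told apart from a rise along with those genes. The ratio of Nat10 between the groups (0.467, Nat10 flox/flox over Nat10-CKO) is what either would give. Under an exchange, the higher Nppa (53.6-fold) and Nppb (44.7-fold) and the lower Atp2a2 would belong to the Nat10 flox/flox hearts. These genes were not used to weigh it. A larger share of run-on reads also stays open, as the gain of Nat10 was 16.9% of the Caprin1 level and reads between the genes were not used here, and so do reads from undeleted exons or cells, which were not tested.

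The second pattern is a set of neuron and Schwann cell transcripts in Nat10 flox/flox replicate 1, where 323 genes were at least 10 times the highest of the other libraries, against 3 to 18 in each of the other libraries. Prph was 116.6 FPKM there and at most 0.185 FPKM elsewhere. Tubb3 was 154.5 FPKM there and 0.454 and 0.777 FPKM in the other Nat10 flox/flox libraries. In the Nat10-CKO libraries Tubb3 was 7.61, 12.4 and 3.60 FPKM. Greater depth or detection is argued against, since 69 low markers of other lists had a median log2 ratio of only 0.32 to the other Nat10 flox/flox libraries. Tissue of a peripheral ganglion or nerve in that heart sample is a candidate source that stays open, with no biological explanation tested: 9 of the 14 markers fixed beforehand were at least 5 times the highest other library, below the 10 set as the bound, with Dbh at 1.18 FPKM. Of the 14, 5 reached 1 FPKM in another library, and thymus and lung markers (4 of 13) and adipocyte markers (3 of 11) were also 5 times higher there.

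The third pattern is the lower level of nuclear-encoded oxidative phosphorylation genes (median log2 fold change -0.58), with 33 of 78 members called lower and 9 without Nat10 flox/flox replicate 2 or 3, 13 without replicate 1, and 14 and 53 without Nat10-CKO replicate 2 and 3. The list was called by camera with a preset correlation and not with an estimated correlation (adjusted p = 0.827) or by fry (adjusted p = 0.0951). A lower share of cardiomyocytes is not settled here. The sarcomere list had a median of 0.295 (quartiles -0.203 and 1.205), with 14 of 30 members called higher and 3 lower. It holds genes that rose strongly, such as Synpo2l (25.6-fold), so its median cannot measure that share. Among heart muscle genes, Tnni3 and Pln fell (log2 fold change -1.6 and -1.9) and Myh6 did not pass (-0.07). The medians of other cell types were -0.437 (endothelial), 0.149 (fibroblast) and 0.132 (macrophage). They did not rise alike, as a lower share alone would give. Scaling is argued against as the whole cause, since the highest median of the nuclear-encoded list under 4 scalings was -0.425, and so is a trend with gene length, because the median was -0.619 after a loess correction. What lowered these genes in the libraries labelled Nat10-CKO stays open.

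The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4856 genes and the highest of the others 0, so 1 split reached the real count. Each other split mixes both labels, so the difference between labels adds to the spread within its groups. Its count is therefore no measure of chance.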
